A study of Harpegnathos saltator with 75 samples.

How the data were processed

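Polyadenylated RNA of the jumping ant Harpegnathos saltator was measured in 75 libraries from 3 tissues (the brain without its visual part, the fat body and the ovary). Each tissue was sampled at day 0 and, at day 3 and day 10, in ants set to become gamergates (workers that mate and lay eggs) or to remain workers. There were 5 libraries in each of the 15 groups. Per the labels' protocols, RNA was extracted with Trizol and treated with DNase, and polyadenylated RNA was selected from about 500 ng of total RNA. Libraries were made with the NEBNext Ultra II RNA kit and sequenced on an Illumina HiSeq. Whether strand was used in counting is not given in the sources used here. The labels do not say that the replicates of a group are separate ants, so p-values measure the spread between these samples.

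The deposited table holds raw read counts per gene, as whole numbers that the authors did not normalize, for 20659 gene models and 75 libraries. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned with STAR 2.5.3a and counted with HTSeq. The genome build and the annotation used are not given in the sources used here. The table also has 5 rows for reads that HTSeq assigned to no gene, and these stayed out of library sizes and tests. Reads outside annotated genes made up 20.7% to 67.7% of a library (median 38.2%), reads aligned to several places 4.07% to 16.6%, and ambiguous reads 0.615% to 2.41%. Reads assigned to genes numbered 488892 to 4677916 per library, with a median of 1380887, and 7200 to 11789 genes per library had at least 5 reads.

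The table gives gene identifiers only. Of these, 0 matched the RefSeq gene table used here for names, so the files do not pair the identifiers with names, and no gene is named or described. The 34 gene lists and the condition on product descriptions that had been set before the data were examined could not be applied. Genes that share reads with near-identical copies, overlapping genes and antisense genes could not be recognised either, so this stays open for each gene printed. In their place, 2 kinds of gene group were made after the data were examined. The first holds genes enriched in 1 tissue at day 0 (log2 fold above 3 against both other tissues, adjusted p below 0.05, mean of at least 10 CPM, where CPM is the count scaled to a library of 1e6 assigned reads). These were 715 genes for the brain, 373 for the fat body and 165 for the ovary. The second holds the genes that differed between castes at day 10, measured again in the day 3 libraries.

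Each tissue was fitted on its own with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15) and libraries were scaled by TMM. The quasi-likelihood test with robust dispersion was applied to all 25 libraries with 1 coefficient per group. The genes tested numbered 9886 in the brain, 7941 in the fat body and 9150 in the ovary, with biological coefficients of variation of 0.272, 0.344 and 0.282. For each tissue the contrasts were gamergate against worker at day 3 and at day 10, the difference between these 2 contrasts, and each later group against day 0. Benjamini-Hochberg adjusted p below 0.05 was the threshold. Log2 fold changes come from this fit, and CPM values use the TMM-scaled library sizes. Standard errors (SE) were computed back from the test, as the absolute log2 fold change divided by the square root of its F statistic. They thus restate the test and are not a separate estimate of spread. The genes printed for a caste comparison are at most 2 per direction with the largest log2 fold change among those past the threshold, with a mean of at least 10 CPM in the higher group and no overlap between the castes. All genes are given where 5 or fewer were called, and the gene with the most reads in the table, HSALG009096.2, was added after its values were seen. Gene groups were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01, and again with an estimated correlation, over a family of 54 tests. Single values per library were compared by two-sided exact permutation tests over 24 comparisons. With 5 against 5 libraries the smallest p is 0.00794. Where a group had 0 reads of a gene, the floor was 3 reads over the whole group, and intervals of ratios are exact binomial intervals at 95%. These cover counting error only.

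The library names carry 2 flow cells and 2 lanes. At day 3 and at day 10, worker libraries were all on lane 1 and gamergate libraries all on lane 2. Each day had its own flow cell, so no caste comparison can be made within a lane. The day 0 libraries were spread over the 4 lanes, which allows a fit with lane as a term. On the day 10 flow cell, day 0 number 3 alone was on lane 1 and number 4 alone on lane 2. On the day 3 flow cell, numbers 1 and 5 were on lane 1 and number 2 on lane 2. For a caste comparison the lane term thus rests on these few day 0 libraries and also takes up differences between them. Alternatives set before the data were examined were DESeq2 size factors, no filter on low counts, and DESeq2 1.42.0 in place of edgeR. The others were the replicate number as a block, lane as a term, a fit on the compared groups alone, and each library left out in turn. Leaving out every library numbered 5, leaving out the brain library numbered 5 at day 0, and the variants of the gene group tests were added after the data were seen. In 150 pairs of libraries within groups, the lowest chi-square per degree of freedom was 1.23 against a median of 11.5, and no library was treated as a duplicate.

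The test was tested on counts simulated for the real genes with 200 changed genes. In the ovary at day 10 (9150 genes), 87.9% of genes changed 4-fold, 50.7% of those changed 2-fold and 14.9% of those changed 1.5-fold were recovered, and 1.92% of the calls were false. For the brain at day 10 (9886 genes) the recovered shares were 89.4%, 47.8% and 8.96%, with 6.73% false calls. For the fat body at day 10 (7941 genes) they were 81.8%, 34.3% and 2.99%, with 5.95% false calls. The real day 10 ovary had 4036 called genes, far more than the 200 changed here, and the adjusted threshold depends on how many genes change. No simulated library was made to stand apart from its group. These shares thus need not hold for the real comparisons, least of all for the day 10 ovary.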

Results

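Workers of Harpegnathos saltator can enter a contest of antennal duels once the colony lacks a reproductive, and the winners become gamergates. Transcript levels were measured in brain, fat body and ovary at day 0 of this contest. They were measured again at day 3 and day 10 in ants on the gamergate path and in ants remaining workers, with 5 libraries per tissue, day and caste (75 in all). A median of 1132015 reads per brain library, 1611587 per fat body library and 1336607 per ovary library were assigned to genes, over a range of 488892 to 4677916. Genes enriched in the fat body at day 0 held 37.6% to 70.4% of the reads in the 25 fat body libraries, 2.29% to 7.47% in brain libraries and 1.69% to 4.40% in ovary libraries.

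**Figure D1:**
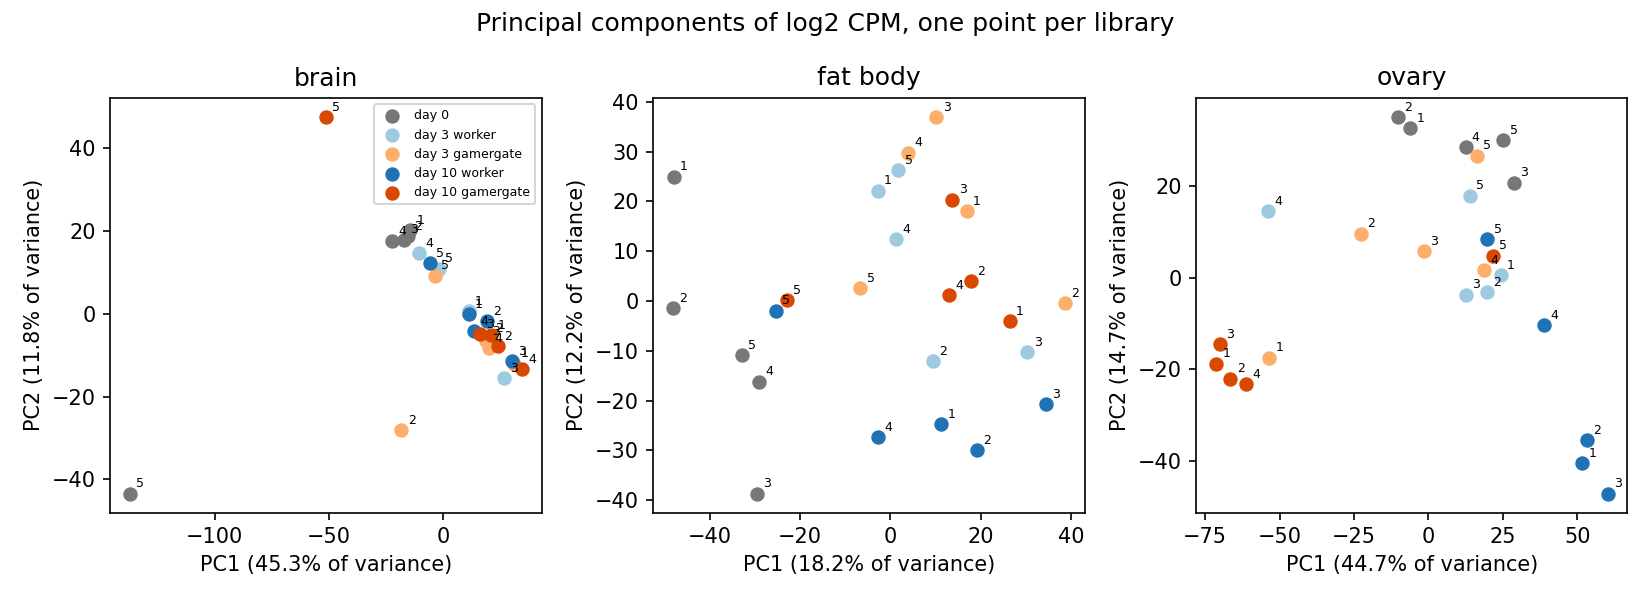
Principal components of log2 CPM for the 25 libraries of each tissue; axes give the share of variance, colours the groups, and the digit beside each point the replicate number. In the ovary 4 day 10 gamergate libraries lie between -71.37 and -61.42 on the first component and the library numbered 5 lies at 21.72.

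The question at day 10 was how far the tissues of the 2 castes had moved apart. By the number of genes called without lane as a term, the ovary differed most. Of 9150 genes tested there, 2069 were higher and 1967 lower in gamergates (edgeR quasi-likelihood test, adjusted p below 0.05), which is 44.1% of the genes tested. More than 2-fold differences were found for 733 of the higher and 922 of the lower genes. The median log2 difference was 0.78 among the higher and -0.94 among the lower genes. Of the 165 genes enriched in the ovary at day 0, 79 were higher in gamergates and 24 lower (83 and 25 adjusted over the list alone), with a median log2 difference of 0.65. Of 180 brain-enriched genes measured in the ovary, 22 were higher and 76 lower (median -0.78). Of 271 fat-body-enriched genes 54 were higher and 102 lower (median -0.32). The camera test gave adjusted p of 0.000266, 4.4e-05 and 0.0385 for these groups, and adjusted p of 0.678, 0.665 and 0.748 with an estimated correlation, so none holds there.

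HSALG013064.2 had 1116 reads in the gamergate ovaries and 0 in the worker ovaries, which is at least 493-fold higher in gamergates against a floor of 3 reads over the worker group (edgeR adjusted p = 0.0314). The limit was 268-fold without worker library 1 and 318-fold without gamergate library 3. Gamergate library 5 was at only 0.7082 CPM, against 157.7 to 442.9 CPM in the other 4 gamergate libraries. HSALG023381.1 had 24257 reads in gamergates and 2 in workers, a ratio of pooled CPM of 16076 with a counting interval of 4450 to 132755 (edgeR adjusted p = 0.0229). Its gamergate libraries ranged from 2.83 to 17563 CPM, and without library 3, which held 22125 of the reads, the ratio was 1821 (503 to 15045). It was 8722 (2414 to 72022) without worker library 1, and without worker library 5, which held both worker reads, the fitted log2 fold change went from 13.47 to 15.79. HSALG004753.2 had 3 reads in gamergates and 2121 in workers, a ratio of pooled CPM of 533 in favour of workers with a counting interval of 182 to 2588 (edgeR adjusted p = 0.000484), and the ratio was 176 (59.7 to 856) without worker library 1. HSALG005766.2 was at 3.35 ± 3.45 CPM against 117 ± 100 CPM (log2 fold change -5.04, SE 1.08, edgeR adjusted p = 0.0012; -5.72 without gamergate library 5). Its level in worker fat body was far higher, so fat body carry-over into worker ovaries stays open for this gene. The call of HSALG023381.1 ended without gamergate library 3 or worker library 1, 2 or 5 (edgeR adjusted p up to 0.0678). That of HSALG013064.2 ended without gamergate library 3 or worker library 1, 2, 3 or 4 (edgeR adjusted p up to 0.0657). Without every library numbered 5 the former call ended (edgeR adjusted p = 0.0501), and without a filter on low counts the latter (0.0565). The gamergate ovary library numbered 5 lay between the castes, with a score on the called genes of 0.0567 against 1.40 to 1.58 in the other 4 gamergates and -1.50 to -0.261 in workers. Without it 4565 genes were called. With lane as a term 1 gene was called. The median difference of the 4036 called genes went from 0.85 to 0.67 on the log2 scale, while their median standard error went from 0.218 to 0.525.

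**Figure D2:**
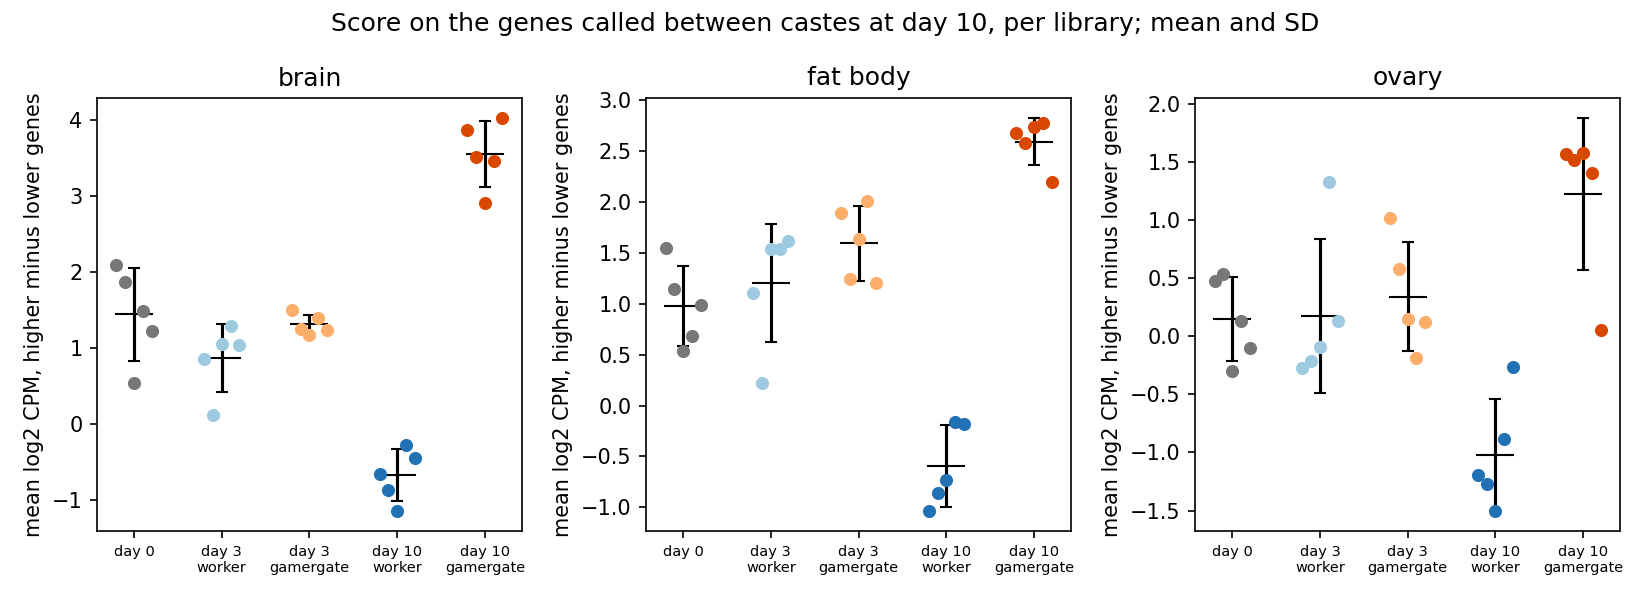
Score of each library on the genes called between castes at day 10 in its tissue (mean log2 CPM of the higher genes minus mean of the lower genes, y axis) by group (x axis); points are libraries, bars mean and SD, and the genes were chosen on the day 10 libraries shown. In the ovary the day 10 gamergates lie at 1.40 to 1.58 except the library numbered 5 at 0.0567.

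In the fat body, the insect organ that stores nutrients and secretes most blood proteins, HSALG009096.2 had the most reads of any gene in 21 of 25 libraries. In day 10 gamergate 5 and day 10 workers 1, 2 and 3 this was HSALG013133.2 (12.7%, 9.36%, 10.8% and 8.45% of reads). HSALG009096.2 took 37.4% ± 15.4 of the assigned reads in day 10 gamergates and 5.64% ± 6.88 in workers (SD, n = 5), against 15.1% ± 2.12 at day 0. The difference had an exact permutation p of 0.0238 (two-sided; 0.0714 after adjustment over 24 tests), with 4 of 5 gamergates above all workers. Those 4 gamergates lay at 43.4% to 44.5%, and the gamergate library numbered 5 at 9.85%. Workers 1, 2 and 3 lay at 0.290% to 1.24%, and workers 4 and 5 at 14.7% and 11.5%, so the worker mean lies between 2 sets of libraries. In the edgeR fit its log2 fold change was 3.39 (SE 0.82, adjusted p = 0.0191), and 4.29 without worker library 4. This call ended without the worker library numbered 1 (edgeR adjusted p = 0.0558), without a filter on low counts (0.0565), and in a fit of the 2 groups alone (0.150). It also ended with lane as a term (log2 fold change 2.85, SE 2.05).

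**Figure D3:**
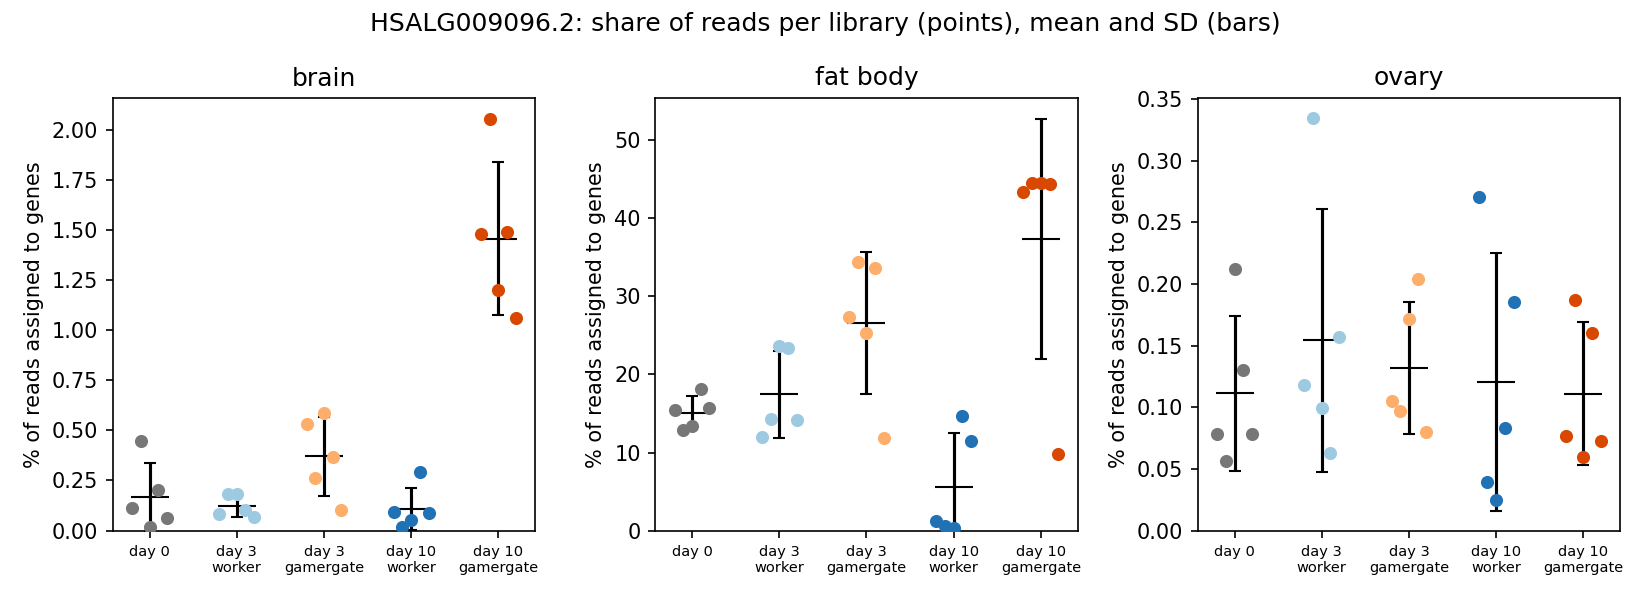
Share of assigned reads taken by HSALG009096.2 (y axis, percent) in each library, by group (x axis) and tissue; points are libraries, bars mean and SD of 5 libraries, and each panel has its own scale. Fat body of day 10 gamergates holds 4 libraries at 43.4% to 44.5% and 1 at 9.85%.

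At day 10, 158 fat body genes were higher and 177 lower in gamergates out of 7941 tested (edgeR quasi-likelihood test), 118 and 139 of them by more than 2-fold. HSALG013065.2 was at 672 ± 165 CPM in gamergates and 4.03 ± 5.11 CPM in workers (SD, n = 5; log2 fold change 7.55, SE 1.30, edgeR adjusted p = 0.00229; 8.79 without worker library 5). HSALG004475.2 was also higher (log2 fold change 7.99, SE 1.73, edgeR adjusted p = 0.0117), but 1 gamergate library at 1167 CPM stood against 4.53 to 18.6 CPM in the other 4. Without it the log2 fold change was 3.50 (edgeR adjusted p = 0.0937), and it was 8.77 without worker library 4. The call also ended with the replicate number as a block (log2 fold change 7.12, SE 2.06, edgeR adjusted p = 0.0654). The same gene reached 174931 to 224907 CPM in 3 of 5 gamergate ovaries and 22.2 to 27.6 CPM in the other 2, against 40.4 ± 11.3 CPM in worker ovaries. Ovary carried over into fat body, or ovary reads of the same lane assigned to the wrong library, were not tested for it and stay open. HSALG022429.1 was lower in gamergates, at 32.9 ± 56.1 against 3785 ± 4535 CPM (log2 fold change -6.82, SE 1.62, edgeR adjusted p = 0.0199). This call ended without gamergate library 1, 3 or 4 (edgeR adjusted p up to 0.0616) and without every library numbered 5 (0.0607). Its log2 fold change was -8.88 without gamergate library 2 and -5.76 without worker library 3. The gene was also lower in gamergate brains (log2 fold change -3.99, edgeR adjusted p = 0.0354) and ovaries (log2 fold change -6.23, edgeR adjusted p = 0.000306). Fat body carry-over was not tested for this gene alone and stays open as a source of its reads in worker brains and ovaries. HSALG002977.2 was at 0.737 ± 0.918 against 41.1 ± 42.1 CPM (log2 fold change -5.60, SE 1.09, edgeR adjusted p = 0.00478; -6.44 without gamergate library 2 and -4.91 without worker library 1). Of 368 fat-body-enriched genes 21 were higher and 21 lower (median 0.08; camera adjusted p = 0.0124, and adjusted p = 0.748 with an estimated correlation).

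The count fell to 153 without the day 10 worker library numbered 1 and to 182 without that numbered 2. It was 174, 201, 178 and 164 without the gamergate libraries numbered 1, 2, 3 and 4. It was 206 in a fit of the 2 groups alone and 25 with lane as a term. Under the lane term the median difference of the called genes went from 1.41 to 1.25 and their median standard error from 0.35 to 0.843. Among day 0 fat bodies, lane 2 minus lane 1, signed by the caste call, had a median of -0.0109 over these genes. The SD over 10 splits of these day 0 libraries was 0.167. On the day 10 flow cell alone, with 1 library per lane, the median was 0.13.

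In the brain 18 genes were higher and 6 lower in day 10 gamergates out of 9886 tested (edgeR quasi-likelihood test). Of these 24, 23 had no overlap between the castes, as had 191 of all genes tested there. Among called genes this held for 196 of 335 in the fat body and 1544 of 4036 in the ovary. These genes were called on the same libraries, so the lack of overlap is not separate evidence. HSALG009096.2 took 1.46% ± 0.381 of brain reads in gamergates and 0.108% ± 0.107 in workers (SD, n = 5; exact permutation p = 0.00794, the smallest possible, and 0.0476 adjusted over 24 tests). All 5 gamergates lay above all workers. Its log2 fold change was 3.83 (SE 0.69, edgeR adjusted p = 0.0074), and in the ovary it was 0.11 (SE 0.58, edgeR adjusted p = 0.894). Without worker brain 4 the brain value was 4.64. The brain call ended without every library numbered 5 (log2 fold change 3.86, SE 0.88, edgeR adjusted p = 0.104) and without a filter on low counts (0.0531). HSALG022417.1 had 128 reads in gamergate brains and 0 in worker brains, at least 55.7-fold higher against a floor of 3 reads over the worker group (edgeR adjusted p = 0.019), and at least 35.3-fold without worker library 2. This call ended without gamergate library 2 or worker library 1, 2 or 5 (edgeR adjusted p up to 0.0709), without every library numbered 5 (0.110) and without a filter on low counts (0.0714). HSALG027442.1 was at 3.07 ± 3.83 against 68.8 ± 33.6 CPM (log2 fold change -4.36, SE 0.63, edgeR adjusted p = 0.0011; -5.33 without gamergate library 3). HSALG013198.2 was at 47.1 ± 10.2 against 198 ± 97.7 CPM (log2 fold change -2.06, SE 0.36, edgeR adjusted p = 0.00635), a call that ended without every library numbered 5 (log2 fold change -1.66, SE 0.46, edgeR adjusted p = 0.209). Of 246 fat-body-enriched genes measured in the brain, 8 were higher and 1 lower (33 and 2 when adjusted over the list alone), with a median log2 difference of 0.31. The camera adjusted p was 8e-14, and the adjusted p was 0.573 with an estimated correlation. These genes together held 5.42% ± 1.21 of reads in gamergate brains and 3.18% ± 0.347 in worker brains, and HSALG009096.2, which belongs to the group, accounted for 1.46% and 0.108% of all reads there. Of 714 brain-enriched genes 3 were higher and 2 lower, with a median of -0.08 (camera adjusted p = 0.000298, and adjusted p = 0.743 with an estimated correlation). Gamergate brain 5 had 10.5% of reads in brain-enriched genes and 7.47% in fat-body-enriched genes, against 16.3% to 17.9% and 4.46% to 5.57% in the other 4.

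The brain count was 46 with DESeq2, which kept all 24 genes, 52 without the day 0 library numbered 5, and 10 in a fit of the 2 groups alone. It was 14 to 15 without the gamergate libraries numbered 1, 2 or 5 or the worker library numbered 1, and 12 with lane as a term, none of them among the 24. Under the lane term the median difference of the 24 genes went from 1.86 to 1.54, with 91.7% in the same direction, and their median standard error from 0.362 to 0.802. For HSALG009096.2 the lane term brought the log2 fold change to 0.23 (SE 1.27). Among day 0 brains its share was 0.448% and 0.201% in the libraries on lane 2 and 0.0157% to 0.113% in the 3 on lane 1. At day 10 the lane term rests on 2 of these alone, number 3 on lane 1 (0.0157%) and number 4 on lane 2 (0.201%).

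At day 3 few or no caste differences passed the test. In the brain 0 genes were called by edgeR and 0 by DESeq2, with 126 genes (1.27% of those tested) at an unadjusted edgeR p below 0.05. In the ovary edgeR called 0 genes and DESeq2 5, with 362 (3.96%) at an unadjusted edgeR p below 0.05. Genes without any difference give a share of about 0.05 there, so neither number points to caste differences. In the fat body 4 genes were lower in gamergates and 0 higher. HSALG013168.2 was at 2.88 ± 1.89 CPM in gamergates and 16.7 ± 5.57 CPM in workers (SD, n = 5; log2 fold change -2.52, SE 0.38, edgeR adjusted p = 0.00193). HSALG028116.1 was at 16.3 ± 7.7 against 50.4 ± 6.7 CPM (log2 fold change -1.63, SE 0.24, edgeR adjusted p = 0.00193). The others were HSALG002490.1 (log2 fold change -1.43, edgeR adjusted p = 0.00202) and HSALG015320.2 (log2 fold change -1.62, edgeR adjusted p = 0.00947). DESeq2 called 12 genes and gave no adjusted p for these 4. A fit of the 2 groups alone called 0 (edgeR adjusted p from 0.115 to 0.285 for the 4 genes), and 7 were called without gamergate library 5 or worker library 3. Without every library numbered 5 the calls of HSALG002490.1 and HSALG015320.2 ended (edgeR adjusted p = 0.119 and 0.136). A fit with lane as a term also called 0; the median difference of the 4 genes went from 1.63 to 2.02 and their median standard error from 0.258 to 0.507.

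Genes of the day 10 difference were measured again at day 3, in other libraries. The 18 brain genes that were higher in gamergates at day 10 had a median log2 difference of 0.34 at day 3, with 88.9% in the same direction (camera adjusted p = 5.37e-09, and adjusted p = 0.00611 with an estimated correlation). Of these 18 genes 8 were fat-body-enriched. The 246 fat-body-enriched genes measured in the brain had a median of 0.14 at day 3, with 0 called (camera adjusted p = 1.56e-06, and adjusted p = 0.665 with an estimated correlation). The 158 fat body genes had a median of 0.26 with 69.0% in the same direction (camera adjusted p = 8.89e-07, and adjusted p = 0.279 with an estimated correlation). That median was 0.16 without gamergate library 4 and 0.12 without worker library 2. The 2069 ovary genes had a median of 0.04 (camera adjusted p = 0.021, and adjusted p = 0.771 with an estimated correlation). This call ended without gamergate library 1 or 2 or worker library 1, 2 or 3 (median -0.02 to 0.03). The ovary median was 0.09 without gamergate library 4 and 0.13 without worker library 4. The genes lower in gamergates at day 10 had medians at day 3 of 0.07 in the brain (6 genes), -0.07 in the fat body (177) and -0.04 in the ovary (1967). None of the 3 passed the camera test (adjusted p = 0.16, 0.275 and 0.16). With 1 library left out, each had fits at an unadjusted camera p below 0.05. These were without worker 2 in the brain (median 0.17), workers 4 and 5 in the fat body (-0.11 and -0.14), and gamergates 3 and 4 and workers 4 and 5 in the ovary (-0.05, -0.08, -0.14 and -0.04). HSALG009096.2 took 0.37% ± 0.197 of brain reads in day 3 gamergates and 0.124% ± 0.0548 in workers (exact permutation p = 0.0238, and 0.0714 adjusted over 24 tests, 4 of 5 gamergates above all workers). By edgeR the log2 fold change was 1.62 (SE 0.63, adjusted p = 1), and with lane as a term it was -0.65 (SE 1.10). In the fat body these shares were 26.5% ± 9.09 and 17.5% ± 5.56 (exact permutation p = 0.111, 0.205 adjusted).

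The change in the caste difference between day 3 and day 10 was tested directly. It passed the threshold for 1828 ovary genes (1042 upward, 786 downward), 13 fat body genes (7 and 6) and 1 brain gene (edgeR quasi-likelihood test). The brain gene was HSALG004952.1, at 52.3 ± 7.78 CPM in gamergates and 41.7 ± 10.6 CPM in workers at day 3 and at 122 ± 34.7 and 18.1 ± 15.1 CPM at day 10 (SD, n = 5; log2 difference of differences 2.47, SE 0.42, edgeR adjusted p = 0.0315). This call ended in 14 of the 20 fits without 1 library. The fat body count was 3 without the day 10 gamergate library numbered 4 and 56 without the day 3 worker library numbered 2, and moved by over 1.5 times in 13 of 20 such fits. It was 101 with DESeq2, 28 in a fit of the 4 groups alone and 6 without every library numbered 5. In the ovary the count fell to 898 without the day 3 worker library numbered 4, and to 1078 and 1148 without the gamergate libraries numbered 4 and 3 at day 3. It fell to 1129 without the day 10 worker library numbered 3, rose to 2774 without the day 10 gamergate library numbered 5, and was 0 with lane as a term. Under the lane term the median difference of the 1828 genes went from 1.05 to 0.99, with 99.3% in the same direction, and their median standard error from 0.288 to 0.668.

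Against day 0, both castes had changed by day 3. In the brain 660 genes were higher and 974 lower in day 3 gamergates, and 35 and 96 in day 3 workers (edgeR quasi-likelihood test). For the fat body these counts were 682 and 496, and 364 and 239. In the ovary they were 888 and 804, and 374 and 282. At day 10 they were 508 and 550 in gamergate brains, 590 and 969 in worker brains, 372 and 243 in gamergate fat bodies and 655 and 407 in worker fat bodies. In the ovary the day 10 counts were 1240 and 1077 in gamergates and 1939 and 2037 in workers. The larger count in day 3 gamergates than in workers does not by itself show a difference between castes, for which 0, 4 and 0 genes passed the direct test. In worker ovaries at day 10, 121 of 271 fat-body-enriched genes were higher than at day 0 and 7 lower, 67 of 180 brain-enriched genes were higher and 1 lower, and 15 of 165 ovary-enriched genes were higher and 46 lower. The share of reads in fat-body-enriched genes was 4.40%, 4.13% and 3.41% in worker ovaries 1, 2 and 3 but 2.06% and 2.41% in 4 and 5, against 1.81% to 2.31% at day 0. These lists were chosen on the day 0 libraries and are not independent evidence here. The adjusted p was 0.573, 0.573 and 0.71 with an estimated correlation (camera). The brain day 0 library numbered 5 had 67.7% of its reads outside genes, against 57.1% to 58.0% in the other 4. Without it the day 3 brain counts were 877 in gamergates and 61 in workers and the day 10 counts 558 and 674. The day 3 brain counts in gamergates and workers were 2745 and 1141 with the replicate number as a block, 3710 and 1302 without every library numbered 5, and 1971 and 462 with DESeq2. They were 263 and 0 in a fit of the compared groups alone, and 759 and 106 without a filter on low counts. The day 10 brain counts in the same order were 7 and 506 in such a fit and 560 and 932 without a filter. Both rose with the replicate number as a block and without every library numbered 5. Other single libraries also moved brain counts by over 1.5 times. Day 3 gamergate brains had 374, 305 and 321 genes without gamergate 1, 3 or 4. Day 3 worker brains had 27, 22, 31 and 83 without worker 1, 2, 3 or 5, 3.1e2 (rounded) without worker 4 and 229 without day 0 library 2. Day 10 gamergate brains had 583, 410, 593 and 477 without gamergate 1, 2, 3 or 4 and 3940 without gamergate 5. Day 10 worker brains had 763, 386, 582 and 669 without worker 1, 2, 3 or 4. Day 3 gamergate fat bodies had 767, 715 and 707 without gamergate 1, 2 or 3 and 742 without day 0 library 2. Day 10 gamergate fat bodies had 312, 349, 323 and 280 without gamergate 1, 2, 3 or 4, 1000 without gamergate 5, and 386 and 369 without day 0 library 2 or 4. Day 10 worker fat bodies had 591, 589 and 512 without worker 1, 2 or 3, 1746 without worker 5, and 657 and 613 without day 0 library 1 or 2. Day 3 gamergate ovaries had 1033 and 898 without gamergate 2 or 3. Day 3 worker ovaries had 182, 392, 201 and 1167 without worker 1, 2, 3 or 4 and 389, 317, 355 and 325 without day 0 library 1, 3, 4 or 5, and 3.0e2 (rounded) without day 0 library 2.

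With lane as a term the count of day 3 worker brains rose to 2209 and the others against day 0 fell, to 2 genes in day 3 gamergate brains and 0 in day 10 worker ovaries. Median differences of the genes called without the term went from 0.92 to 0.70 in day 3 gamergate brains and from 0.74 to 0.65 in day 10 worker ovaries, with 98.1% and 99.4% in the same direction. Their median standard errors went from 0.266 to 0.459 and from 0.197 to 0.347.

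**Figure D4:**
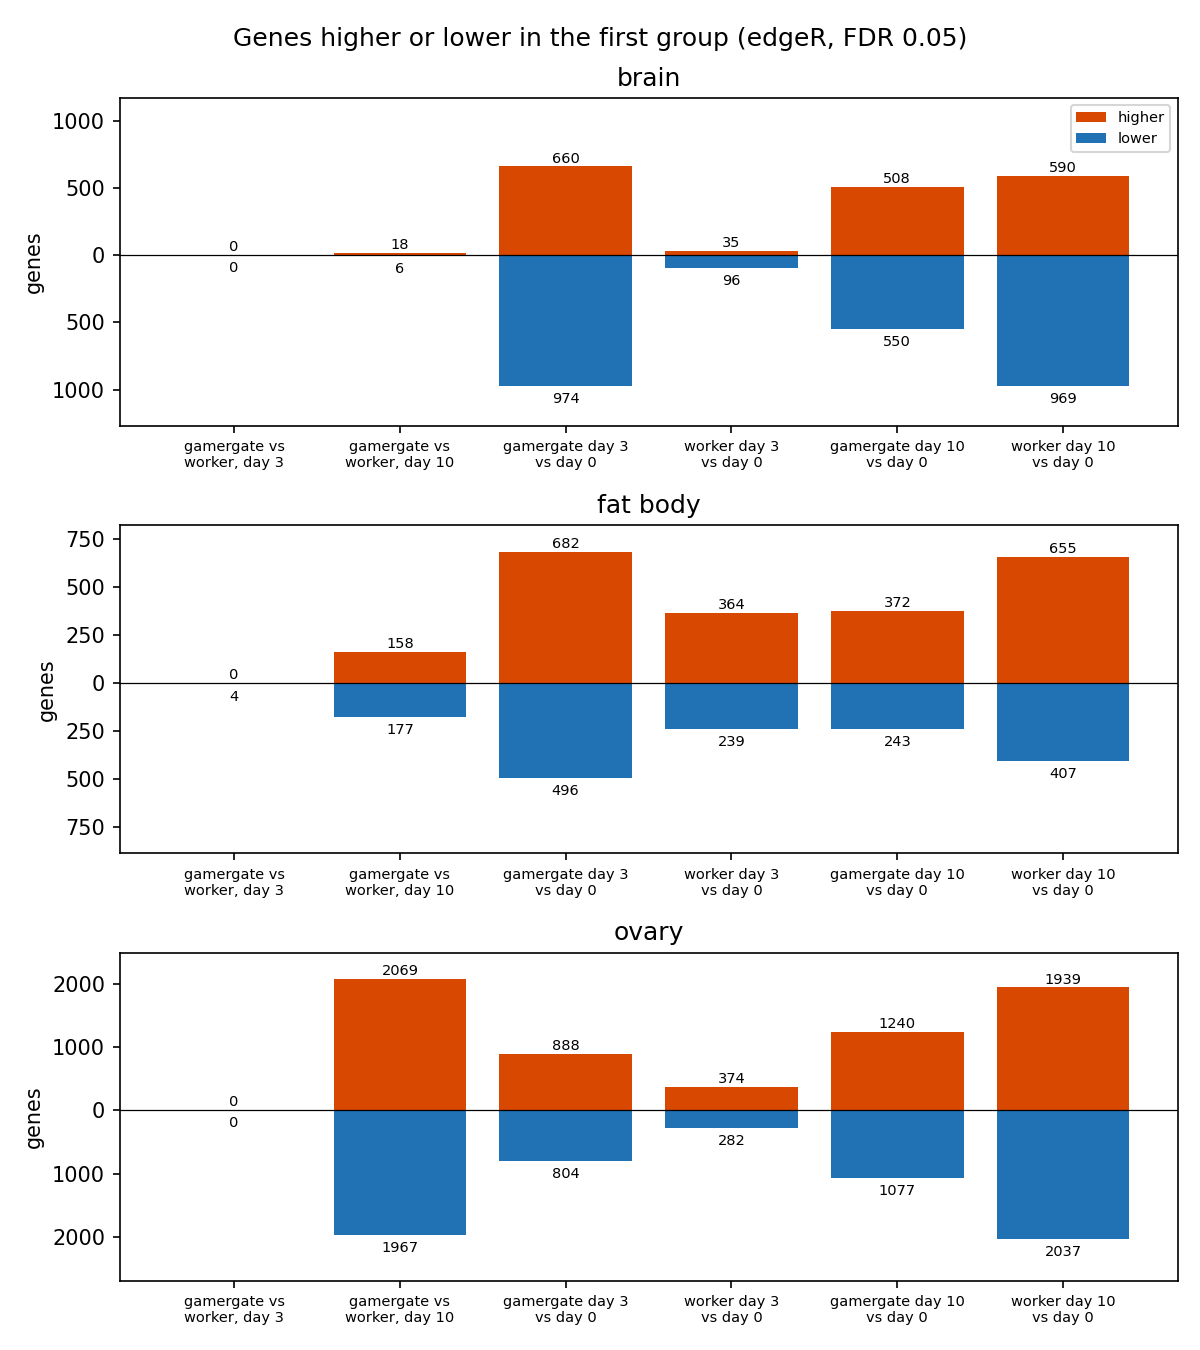
Number of genes (y axis) higher (above 0) or lower (below 0) in the first group of each comparison (x axis) by the edgeR test at an adjusted p of 0.05, in 3 tissues with their own scales. The caste comparison gives 2069 higher and 1967 lower genes in the day 10 ovary and 0 in the day 3 ovary.

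The 2 castes were compared with the same day 0 libraries, so their changes share chance values. In the ovary at day 10 the changes from day 0 had a correlation across genes of 0.0918 and a covariance of 0.0512, against 0.447 and 0.0463 in simulated groups without any effect. The correlation was 0.049 when the day 0 libraries were split between the castes; genes are not independent replicates. In the brain at day 10 the correlation was 0.859 and the covariance 0.324, against 0.467 and 0.0435 simulated and 0.562 with split day 0 libraries. For fat body at day 10 these values were 0.576 and 0.241, against 0.468 and 0.0631 simulated and 0.345 split. At day 3 the correlations were 0.921, 0.848 and 0.827 in brain, fat body and ovary (simulated 0.481, 0.465 and 0.474; split 0.577, 0.579 and 0.611). The covariances were 0.303, 0.361 and 0.194 (simulated 0.0425, 0.0631 and 0.0487). In the ovary at day 10, 362 genes were higher than day 0 in both castes, where independent lists of these sizes share 263. Lower in both were 439 genes, where such lists share 240, and 119 genes moved in opposite directions. In the brain 285 and 384 genes were shared (independent lists 30.3 and 53.9, 0 opposite) and in the fat body 164 and 71 (30.7 and 12.5, 2 opposite). Simulated groups without effect shared 0 calls. Such groups hold few calls to share, so this does not measure what the common day 0 libraries add to the overlaps.

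Caste differences at day 10 were set side by side between tissues over the genes tested in both. Brain and fat body shared 4 higher genes, where independent lists share 0.218, and 2 lower genes, where they share 0.0817. Fat body and ovary shared 22 higher genes (29.6 for independent lists) and 49 lower genes (33.6), and 62 genes differed in opposite directions (63.4). Brain and ovary shared 1 higher gene (2.59) and 3 lower genes (0.866), and 6 genes differed in opposite directions (3.46). In all 3 tissues 3 genes were called, of which 2 were lower in gamergates in each.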

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

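Tests chosen only after their results were seen were those of fat body carry-over into gamergate ovaries, of the wrong ant, the swapped ovary and the shared condition of libraries numbered 5, of the shift of the whole fat-body-enriched group in the brain, and of reads assigned to the wrong library. The tests of lane in the ovary, of fat body carry-over into worker ovaries and of equal carry-over in the brain were written before. So were those of carry-over as the source of the most abundant gene's rise and of other splits of the libraries. The lane values over the called brain genes had no prediction written before.

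The ovary at day 10 had 4036 genes that differed between castes. Lane was tested in the day 0 ovaries, which were spread over lanes: lane 2 minus lane 1, signed by the direction of the caste call, had a median of 0.116 on the log2 scale, below 0.5 of the caste median (0.426) by more than the 0.121 SD of the 10 splits of these libraries, and the second flow cell alone, with 1 library per lane, gave 0.177. Fat body carried into gamergate ovaries is argued against by the 20 most abundant fat-body-enriched genes, of which 18 were lower in gamergate ovaries (median -1.874, bootstrap SE 0.81), and fat body carried into worker ovaries reached 0.5 of the excess for 4.17% of the 1967 genes higher in workers, at the largest carry-over of the 5 libraries (4.81%). With lane as a term 1 gene was called. The median standard error of the 4036 genes went from 0.218 to 0.525 and their median difference from 0.85 to 0.67. That term rests on 1 day 0 ovary per lane of the day 10 flow cell. A library preparation batch that followed the groups cannot be told apart from caste, and caste itself, which the design names, stays open as a hypothesis.

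The day 10 gamergate ovary numbered 5 stood apart, at 31.2 on a scale from the worker mean (0) to the mean of the other gamergates (100), where the other 4 lay at 107 to 115. A worker ant under this label is argued against if the libraries numbered 5 are 1 ant, which the labels do not say: the brain lay at 98.7 and the fat body at 71.5, outside the worker range. A swap with a day 10 worker ovary needs a worker among the gamergates. The highest worker ovary, number 5, lay at 47.3 when left out alone. It lay at 38.8 when left out together with gamergate 5, below the other gamergates at 95.4 to 102. The second version of this test was made after the first gave a value close to its bound. In that version gamergate 5 also lay at 38.8, above the other workers at -11.1 to 13.4. Exchanged labels of these ovaries numbered 5 would leave the positions alike, so the test cannot decide on a swap between them. A condition shared by libraries numbered 5 may be part of why this gamergate ovary stood apart. Libraries numbered 5 were closest to day 0 in 9 of 12 groups, and in 8 of 11 without that ovary group. Their mean rank by closeness to day 0 was 1.5 with and without that group (exact one-sided permutation p of the mean rank = 0.008 in each). This p was not adjusted for the choice of number 5, which was made after it stood apart. The day 0 mean also includes the day 0 libraries numbered 5. A slower course in this ant and a wrong label of the ovary alone, with a sample outside these groups, stay open and untested.

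Of 246 fat-body-enriched genes, 8 were higher and 1 lower in day 10 gamergate brains (33 and 2 adjusted over the list alone; camera adjusted p = 8e-14, and adjusted p = 0.573 with an estimated correlation), with HSALG009096.2 at a log2 difference of 3.83. A larger amount of fat body carried over was tested as the only source of that gene's rise. The 130 fat-body-enriched genes that did not differ in the fat body had a median of 0.317 in the brain (bootstrap SE 0.04). This was below 0.5 of the rise (1.91), but it cannot decide the question. Carry-over adds to each gene's own brain level, so it need not raise all genes equally on the log2 scale. Reads assigned to the wrong library of the same lane are argued against. The ovaries of the same lanes gained -0.00962 percentage points where the brain gained 1.35. More carry-over as the source of the group's shift may remain, since 77.7% of those 130 genes were higher in gamergate brains. Carry-over of a changed fat body, in which HSALG009096.2 itself was higher by 3.39, cannot be told apart from a change within the brain, whether the amount was equal or also larger: genes over 2-fold different in the fat body had a signed median of 0.421 in the brain (SE 0.115), between the bounds of 0.408 and 0.816. Lane stays open for HSALG009096.2, whose difference was 0.23 (SE 1.27) with lane as a term, while lane 2 minus lane 1 among day 0 brains, signed by the caste call over all 24 called brain genes, had a median of -0.0492 (SD of 10 splits 0.218).

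Of 122 sets of 5 libraries, 19 had 1 library far from the others, with a gap to the next of over 0.71 of the range of the set. Chance gives 6.1 if values are normally distributed. This need not hold, as for genes with 0 reads in most libraries, and measures of the same library go together. These numbers are therefore not a test. Among day 0 brains number 5 had 67.67% of reads outside genes (others 57.05% to 58.03%), 8.346% aligned to several places and a first principal component of -137.1. Among day 10 gamergates, number 5 had 8.992% aligned to several places and a first component of -51.42 in the brain. In the fat body it had 33.02% of reads outside genes, 9.854% for HSALG009096.2, 36.28% in the 10 most abundant genes and a first component of -22.97. In the ovary its first component was 21.72 (others -71.37 to -61.42). In day 3 gamergate fat body, number 5 had 36.26% of reads outside genes (others 26.83% to 27.85%). Elsewhere, day 10 worker brain 4 had 0.2908% for HSALG009096.2, day 10 worker ovary 1 had 3558381 assigned reads and day 3 gamergate ovary 1 had 13.04% of reads in its 10 most abundant genes. Day 3 worker ovary 4 had a first component of -53.86 (others 12.71 to 24.31). Single genes with such a library were HSALG002490.1 (20.99 CPM in day 3 gamergate fat body 4), HSALG004475.2 (1167 CPM in day 10 gamergate fat body 2), HSALG023381.1 (2.273 CPM in day 10 worker ovary 5, others 0) and HSALG013064.2 (0.7082 CPM in day 10 gamergate ovary 5, others 157.7 to 442.9).

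The caste difference changed between day 3 and day 10 for 1 brain gene, 13 fat body genes and 1828 ovary genes (edgeR). The log2 difference of differences was 2.474 for HSALG004952.1 in the brain. In the fat body it was 2.951 for HSALG013168.2, 1.831 for HSALG028116.1, 1.511 for HSALG002490.1 and 1.875 for HSALG015320.2, the 4 genes lower in day 3 gamergates (edgeR adjusted p = 0.0109, 0.0154, 0.0276 and 0.0304). Reads aligned to several places, outside the gene counts, made up 12.42% ± 1.70 of day 10 gamergate fat body libraries and 8.31% ± 0.938 of worker libraries (SD, n = 5; exact permutation p = 0.00794, 0.0476 adjusted over 24 tests, with 5 of 5 gamergates above all workers).

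Other splits of the same libraries were drawn, 100 for each count, the real one included. For 13 of the 21 counts, a result as large came from 1 split, the real one. This argues against chance for each taken alone, without adjustment over the 21 counts, and does not exclude it. These 13 are listed next. In the brain these were 24 genes between castes at day 10 (highest other split 3), 1634 and 131 for day 3 gamergates and workers against day 0 (224 and 19) and 1559 for day 10 workers (54). In the fat body they were 335 between castes at day 10 (56), 1178 and 603 at day 3 (279 and 73), and 615 and 1062 at day 10 (147 and 648). In the ovary they were 4036 between castes (3873), 1692 and 656 at day 3 (677 and 295) and 3976 for day 10 workers (2978). For 6 other counts 2 to 4 splits were as large. Their shares are under 0.05 only when each is taken alone, without adjustment over the 21 counts. At least 1 other split gave as many genes or more. For the change of the caste difference these were 1 brain gene (3 splits, highest other 4), 13 fat body genes (3 splits, 34) and 1828 ovary genes (3 splits, 4271). The others were 4 fat body genes between castes at day 3 (2 splits, 88), and day 10 gamergates against day 0 with 1058 brain genes (4 splits, 3577) and 2317 ovary genes (3 splits, 2493). For the change of the caste difference, castes were exchanged within each day, so a split can still hold the real day 10 caste difference. Those shares thus do not measure chance for the change itself. For the 0 genes between castes at day 3 in brain and ovary, any split is as large by construction (100 of 100; highest other 0 and 9), so the splits say nothing about chance there. Splits with 2 or more times the real count may point to a structure of the samples, except those of 4 and 34 genes. That of 3577 genes put the day 10 gamergate brain 5 with day 0 brains 2, 3, 4 and 5. That of 88 genes put day 3 gamergate fat bodies 1 to 4 with worker 3, and that of 4271 genes put day 10 gamergate ovaries 1 to 4 with worker 5. Those of 4 and 34 genes put all 5 day 10 workers on the gamergate side, with 3 day 3 gamergates and 2 workers in the brain and 2 and 3 in the fat body. They thus hold the real day 10 castes with the sign turned. Among splits near the real count, that of 3873 genes put day 10 gamergate ovaries 1 to 4 with worker 5, and that of 2493 genes put them with day 0 ovary 1.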

How the results depend on the processing

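Leaving out every library numbered 5, leaving out the day 0 brain numbered 5, and the variants of the gene group tests were chosen after the data were seen. A result past its threshold in either fit changed direction in 4 cases. Fat-body-enriched genes turned from up to down between castes in the day 10 fat body with lane as a term (adjusted p = 0.979 by camera) and from down to up in day 10 worker fat body against day 0 (adjusted p = 0.0216 by camera). The day 3 median of the genes higher in day 10 gamergate ovaries was -0.017 without day 3 gamergate 1 and -0.001 without day 3 worker 1 (0.133 without worker 4). Values past no threshold also changed sign, such as HSALG009096.2 in the day 10 ovary (-0.19 to 0.72 with 1 library left out). With DESeq2 size factors all 21 counts of genes stayed within 1.5 times. In what follows, a group name alone means its count against day 0. Where a count moved further the cause was not tested unless stated. Without a filter on low counts 7 counts moved: day 3 gamergate brain 759, day 10 gamergate brain 560 and day 10 worker brain 932. The others were day 3 gamergate fat body 754, day 10 gamergate fat body 379, day 3 worker ovary 3.1e2 (rounded), and the ovary's change of caste difference 1206. DESeq2 moved 7: castes in the day 10 brain 46, the day 3 fat body 12 and the day 3 ovary 5. The others were change of caste difference in the brain 3 and the fat body 101, day 3 worker brain 462 and day 3 worker ovary 1054. A fit on the compared groups alone, which has fewer libraries to estimate the spread, moved 10: castes in the day 10 brain 10, the day 3 fat body 0 and the day 10 fat body 206. The others were the fat body's change of caste difference 28, day 3 gamergate brain 263, day 3 worker brain 0, day 10 gamergate brain 7, day 10 worker brain 506, day 10 worker fat body 393 and day 3 worker ovary 276.

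With lane as a term, which raised median standard errors 2.12 to 2.41 times between castes and 1.31 to 1.77 times against day 0, 18 of 21 counts moved. Between castes they were 1 in the brain at day 3 and 12 at day 10, 0 in the fat body at day 3 and 25 at day 10, and 1 in the ovary at day 10. The ovary's change of caste difference had 0. Against day 0 they were 2 and 2209 in day 3 gamergate and worker brains and 3 and 26 at day 10. In fat bodies they were 20 and 169 at day 3 and 4 and 104 at day 10, and in ovaries 7 and 16 at day 3 and 15 and 0 at day 10. The replicate block moved 5 counts, in the brain: change of caste difference 3, day 3 gamergate 2745, day 3 worker 1141, day 10 gamergate 2038 and day 10 worker 2629. Numbers did not pair the libraries throughout: 35 of 90 same-number correlations of deviations were over 0.1 (range -0.642 to 0.445). Of these 90, 17 were the best for their library, and 0 of 18 comparisons had every pair over 0.1. In the brain, 4 of 5 pairs of gamergates with day 0 were over 0.1 at each day. For workers with day 0 these were 2 of 5 at day 3 and 3 of 5 at day 10. Variation shared by number in the brain stays open. Without every library numbered 5, 11 counts moved: day 3 gamergate and worker brain 3710 and 1302, day 10 gamergate and worker brain 3839 and 3124, and day 10 gamergate and worker fat body 1288 and 1794. The others were day 3 gamergate and worker ovary 2563 and 1211, and change of caste difference 5 in the brain, 6 in the fat body and 3225 in the ovary. Without the day 0 brain numbered 5, castes in the day 10 brain had 52.

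Leaving out 1 library at a time moved 96 of 240 counts. Between castes the ranges were 14 to 25 in the day 10 brain, 4 to 7 and 153 to 390 in the day 3 and day 10 fat body, and 3383 to 4565 in the day 10 ovary, with 0 in the brain and ovary at day 3. The change of caste difference ranged from 0 to 3 in the brain, 3 to 56 in the fat body and 898 to 2774 in the ovary. Against day 0, the brain ranged from 305 (without gamergate 3) to 1859 in day 3 gamergates and 22 (without worker 2) to 3.1e2 (rounded, without worker 4) in day 3 workers. At day 10 it ranged from 410 (without gamergate 2) to 3940 (without gamergate 5) in gamergates and 386 (without worker 2) to 1762 in workers. The fat body ranged from 707 to 1598, 412 to 559, 280 to 1000 and 512 to 1746 in the same order. The ovary ranged from 898 to 2329, 182 to 1167, 1651 to 3364 and 2982 to 4610. Of 54 gene group tests, 30 lost their call with an estimated correlation, with lane as a term 11 lost and 3 gained one besides the 2 that changed direction, and with the replicate block 3 lost and 1 gained one. Of the single genes, all 18 calls ended with lane as a term and 0 with DESeq2 size factors. Calls that ended without a filter were HSALG022417.1 in the brain, HSALG009096.2 in brain and fat body at day 10, and HSALG013064.2. With the replicate block it was HSALG004475.2 in the fat body. In a fit on the compared groups alone they were the 4 day 3 fat body genes and HSALG009096.2 in the day 10 fat body. Without every library numbered 5 they were HSALG022417.1, HSALG009096.2 and HSALG013198.2 in the brain, HSALG002490.1 and HSALG015320.2 in the day 3 fat body, HSALG022429.1 in the fat body and HSALG023381.1 in the ovary. At a median of 1380887 reads per library and 5 libraries per group, 2.99% to 16.4% of simulated 1.5-fold changes were recovered.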

Other observations

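Tests in this part were chosen after the result was seen. Day 10 worker ovaries were uneven in the share of reads held by gene groups of other tissues. Worker libraries 1, 2 and 3 had 4.40%, 4.13% and 3.41% of reads in fat-body-enriched genes, and libraries 4 and 5 had 2.06% and 2.41%, within the 2.01% to 2.43% of gamergates. As group means, fat-body-enriched genes held 3.28% ± 1.03 against 2.24% ± 0.157 and brain-enriched genes 0.632% ± 0.183 against 0.409% ± 0.0539, while ovary-enriched genes held 3.36% ± 0.992 against 4.57% ± 0.641 (SD, n = 5; these shares were not tested). HSALG005766.2, lower in gamergate ovaries, was at 2130 ± 845 CPM in day 10 worker fat body and 1149 ± 203 CPM in gamergate fat body. At the largest carry-over share among worker ovaries (4.81%), that worker level passes 0.5 of the excess of this gene in worker ovaries.

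Day 3 ovaries were spread widely on the genes that differed between castes at day 10. Gamergate library 1 had a score of 1.02 and worker library 4 a score of 1.32, near the 1.40 to 1.58 of 4 day 10 gamergates, while the other day 3 libraries lay between -0.275 and 0.581. HSALG004475.2 reached 8198 CPM in 1 of the 5 day 3 gamergate ovaries, where the median was 5.40 CPM.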
